A study of Mus musculus with 48 samples.

How the data were processed

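The series holds 48 samples of mouse liver, named in its title as a study of bookmarking, the marking of genomic sites by transcription factors early in development. Analysed here were 20 peak lists from chromatin immunoprecipitation with sequencing (ChIP-seq) and 8 RNA sequencing libraries. The peak lists cover C/EBPα and HNF4α, the liver transcription factors encoded by Cebpa and Hnf4a. There were 2 replicates of each factor at embryonic days 15.5 and 18.5 (E15.5, E18.5) and at postnatal days 0.5, 14 and 60 (P0.5, P14, P60). The RNA libraries came from 3 wild-type (WT) livers, 3 livers that lacked C/EBPα and 2 that lacked HNF4α. In the knockouts, Cre recombinase under the Alfp promoter, active in the liver lineage, deletes a copy of the gene flanked by loxP sites. The remaining 20 ChIP samples, 10 of RNA polymerase II and 10 of input DNA, were not used here.

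The submitters' processing notes name bcl2fastq, FastQC, BWA, TopHat2, Cufflinks, bedtools and DESeq, with no role for most of them, MACS 1.4 for peak calling, and the mouse genome build mm9. The deposited RNA values are treated as a score per gene: reads divided by a size factor per library and rounded to whole numbers, which the submitters name DESeq-normalized in the deposited table. The table lists 37583 Ensembl genes with positions, strand and GC content; its annotation version is not stated, and 8 of 8 files per sample matched their columns of it. A step per read was fitted to missing and doubled whole numbers among the low values, from which between 14.0 and 32.5 M reads per library were estimated. In the 4 libraries with a step above 1, 99.15% to 99.81% of values from 1 to 300 fell on rounded multiples of it, which cover 62.7% to 89.7% of whole numbers. In the other 4 every whole number is such a multiple, so this share does not test the step there. The deposited totals ranged from 13.4 to 26.0 M normalized reads. Each deposited peak list gives start and end positions; the score column is 0 throughout, so no peak height or significance was used. Both HNF4α lists at P0.5 were identical and were taken as 1 library, which left 19 distinct lists.

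Genes were kept with a value of at least 10 in at least 2 libraries, which left 17771 genes. Values were analysed as log2(value + 1). A test for raw counts had been planned; since the values are normalized and rounded, limma 3.58.1 was used in its place, with a trend of the variance on expression, in R 4.3.3. All 8 libraries entered 1 fit with a term for group, and 3 contrasts were tested: the C/EBPα knockout minus WT, the HNF4α knockout minus WT, and the C/EBPα knockout minus the HNF4α knockout. Tests were 2-sided, with Benjamini-Hochberg adjusted p under 0.05 over all genes as the threshold. Log2 changes are given ± standard error (SE); values per group are means ± standard deviation (SD) where marked. For genes near 0 in a group the log2 change depends on the added 1.

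Tested on simulated data with the observed spread, the C/EBPα contrast recovered 4.3% of genes changed 2-fold, 59% of 4-fold, 90.7% of 8-fold and 97.3% of 16-fold changes. For the HNF4α contrast these shares were 1.7%, 43.9%, 84.2% and 96.5%. Of the calls in these simulations, 5.7% and 5.8% were wrong, and 2.5% and 0.5% of unchanged lists passed an unadjusted p under 0.05. Genes varied independently in the simulations and the unchanged lists were random. These shares therefore do not test lists whose members vary together, with estimated correlations of up to 0.54 (complement).

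There were 18 pathway lists: bile acid synthesis and transport, glucose and glycogen metabolism, urea cycle and amino acid catabolism, apolipoproteins and lipoprotein metabolism, plasma carrier proteins, blood coagulation, complement, acute phase, cytochrome P450 and xenobiotic metabolism, fatty acid oxidation and ketogenesis, fatty acid and triglyceride synthesis, cholesterol synthesis, fetal liver genes, liver transcription factors, cell cycle, epithelial junctions, male-biased and female-biased liver genes. The 8 lists of markers of other cells were erythroid cells, bile duct cells, endothelial cells, macrophages, stellate cells and fibroblasts, lymphocytes, neutrophils and granulocyte precursors, and megakaryocytes. They were tested with camera from limma at a preset correlation of 0.01 between genes, adjusted over 78 tests, with an estimated correlation and fry as alternatives. Another 6 lists (pancreatic acinar cells, skeletal muscle, smooth muscle, stomach, intestine, kidney tubule) were chosen after seeing the data. At most 6 members of a list stood in another list (cytochrome P450 and xenobiotic metabolism). All measured members of the 26 lists had a mean of 10 or more in WT liver, except 1 of that list and 1 lymphocyte marker.

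Peaks of both replicates were merged with interval code written in Python. A region counted as bound at a stage when it held a peak of each replicate, with an overlap of at least 1 bp. Similarity of lists was measured as the Jaccard index in base pairs, with an exact permutation test over 945 groupings. Overlaps were set against regions shuffled within chromosomes, 100 times for co-binding and 20 times for retention. A gene counted as bound when a region lay within 5 kb of its transcription start site (TSS). A single TSS was taken per gene, the end where its strand begins in the deposited annotation, and other start sites were not examined. The interval code gave the values of bedtools 2.31.1, or the known values, in 6 of 6 checks on simulated lists. Fisher's exact test compared called with not called genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the remaining work.

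The comparisons, the 26 lists, the thresholds and the rule for named genes were fixed before the data were examined, apart from the change of test. The rule names Cebpa and Hnf4a in each library, then per comparison the 10 genes with the largest rise and the 10 with the largest fall. These had to pass the threshold, have a mean of at least 5 per M normalized reads and show no overlap between groups; predicted models, antigen receptor segments, genes on chromosome Y and Xist were passed over. From each list the rule takes up to 4 members with the largest changes past the threshold, or the 2 most expressed where fewer than 2 pass. For binding it takes Alb, Cebpa, Hnf4a, Afp, Cyp7a1, Cps1, G6pc, Apoa1 and genes with the largest changes; regions could not be ranked, since all scores are 0. Where 5 or fewer members of a list passed in 1 direction, members beyond the rule are also named. These, the examples shared by both knockouts, and the members of the 6 later lists were named after their values were seen. Results of some genes that this rule names are not reported here.

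Alternatives were library totals in place of the deposited scaling, no filter, quantile normalization, removal of a GC trend, other added constants, a replicate block, only the groups compared, each library left out in turn, and for peaks another overlap, distance or use of replicates. Xist and 4 genes of chromosome Y were read as a check of the labels and used in no test. Reads shared between members of the Amy2a, Cyp2c, Cyp3a, Cyp4a, Serpina3 and globin families were assigned in a way that the deposited table does not state, so values of single members are uncertain.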

Results

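RNA levels were measured in 8 liver libraries: 3 WT, 3 C/EBPα knockout and 2 HNF4α knockout. The normalized totals were 22.5, 22.4 and 20.4 M reads in WT, 13.4, 16.1 and 16.4 M in the C/EBPα knockout, and 26.0 and 20.0 M in the HNF4α knockout, in the order of the replicate numbers. The 10 most abundant genes, led by Alb (albumin), globins, H19 and Afp (alpha-fetoprotein), took between 18.3% and 37.6% of these totals. The sample labels give the age of the RNA samples as 60 days after birth and the series text gives E18.5. In WT, Afp was at 499143 to 706964 and H19 at 303520 to 724668. These were 2.23% to 3.47% and 1.35% to 3.23% of the totals, and Igf2 took 0.47% to 0.9%. All 15 measured genes of the fetal liver list had a mean of 10 or more in WT. Such levels of Afp, H19 and Igf2 in all 3 WT libraries argue against an age of 60 days. Binding was measured at 5 stages for each factor, with 13434 to 121624 peaks per C/EBPα list and 21262 to 53278 per HNF4α list.

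The targeted genes were read first. Cebpa (ENSMUSG00000034957), the gene of C/EBPα, was at 9999, 9594 and 5511 in WT and at 322, 419 and 998 in the C/EBPα knockout, 6.93% of the WT mean (log2 -3.98 ± 0.44, n = 3 and 3, adjusted p = 0.000413). In the HNF4α knockout it was at 3886 and 4500, 50.1% of the WT mean, which did not pass (-0.95 ± 0.49, n = 2 and 3, adjusted p = 0.299). Hnf4a (ENSMUSG00000017950) was at 9098, 4948 and 6718 in WT and at 1238 and 2444 in the HNF4α knockout, 26.6% of the WT mean (-1.95 ± 0.45, adjusted p = 0.033). In the C/EBPα knockout Hnf4a was at 2492, 2530 and 4510, 45.9% of the WT mean, and did not pass (-1.14 ± 0.40, adjusted p = 0.188). Reads from parts of Hnf4a outside the deleted segment may be included in these values.

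**Figure D1:**
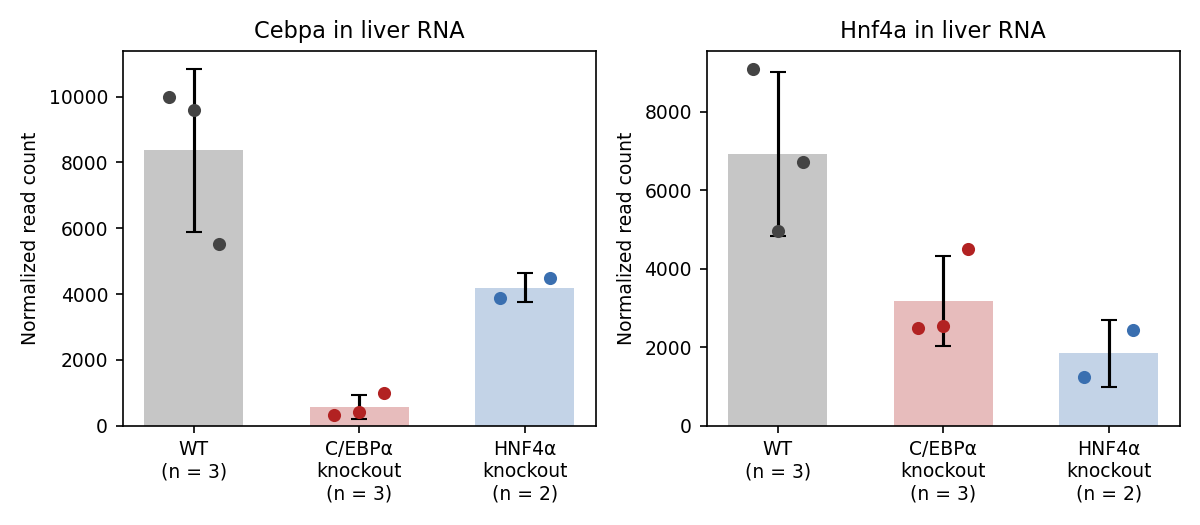
Normalized read counts of Cebpa and Hnf4a in each of the 8 RNA libraries (points), with group means (bars) and SD (lines). Cebpa lies at 322 to 998 in the C/EBPα knockout and at 5511 to 9999 in WT, and Hnf4a at 1238 and 2444 in the HNF4α knockout.

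The comparison of C/EBPα knockout with WT livers asks which RNA levels differ when C/EBPα is missing. In the knockout, RNAs of urea cycle, bile acid and drug metabolism enzymes were lower. Cps1 (ENSMUSG00000025991, chromosome 1, 67169600 to 67277833), the enzyme of the first step of the urea cycle, fell 197-fold (log2 -7.62 ± 0.59, n = 3 and 3, adjusted p = 4.54e-05). Slc10a1, the main bile acid uptake carrier of hepatocytes, fell 123-fold (-6.94 ± 0.35, adjusted p = 5e-06). Serpina6, which encodes corticosteroid-binding globulin, rose 148-fold (7.21 ± 0.47, adjusted p = 2.48e-05), and 4 of 9 bile duct markers rose. In all, 157 genes were higher and 509 lower, 76.4% of 666, each at least 2-fold and with no overlap between the groups. Without overlap were 18.8% of all genes tested, against a share of 10% that chance gives for 3 against 3.

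The 10 largest rises were in Cldn18, Bpifb1, Serpina6, Cdh16, Lgals2, Mir692-1, Cym, Car7, Cldn4 and Clic6. Cldn18, a claudin of tight junctions, was listed at 0 in the 3 WT libraries and at 519, 239 and 570 in the knockout (adjusted p = 7.07e-05). Bpifb1, a secreted protein of airway epithelium, was at 1, 0 and 1 in WT and at 523, 198 and 919 in the knockout. The cadherin gene Cdh16 rose from a mean of 1.7 to 263, the galectin gene Lgals2 from 2.3 to 324.7, and the microRNA gene Mir692-1 (ENSMUSG00000076218, chromosome 17, 7099578 to 7099686) from 14 to 1996.3. Cym, the milk-clotting protease chymosin, rose 46.9-fold (5.55 ± 0.71), Car7, a carbonic anhydrase, 44.9-fold (5.49 ± 0.64), and Clic6, a chloride channel gene, 40.7-fold (5.35 ± 0.65). Cldn4, another claudin, rose 40.8-fold (5.35 ± 1.11, adjusted p = 0.0213); without C/EBPα knockout replicate 3 it did not pass (adjusted p = 0.0579).

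The 10 largest falls were in Cyp3a25, Serpina3k, Hfe2, Cps1, Saa4, Cyp2a4, Aldh8a1, Hpd, Sult3a1 and Pon1. Cyp3a25, a cytochrome P450, fell 308-fold (-8.27 ± 0.82) and Serpina3k, a secreted protease inhibitor, 245-fold (-7.94 ± 0.91). Hfe2, which encodes the iron regulator hemojuvelin, fell 204-fold (-7.67 ± 1.02), and Aldh8a1, an aldehyde dehydrogenase, 169-fold (-7.40 ± 0.52). Pon1, the paraoxonase carried on high-density lipoprotein, fell 157-fold (-7.29 ± 0.66). These 10 genes passed with each library left out in turn, as did 9 of the 10 largest rises.

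Of 26 urea cycle and amino acid catabolism genes, 18 fell and none rose (23 adjusted over the list alone; median -1.89, camera adjusted p = 1.88e-29). With Cps1, these included Hpd and Hgd, enzymes of tyrosine breakdown (-7.38 ± 0.34; -6.27 ± 0.54), and Hal, of histidine breakdown (-6.70 ± 0.45). Of 20 bile acid genes, 13 fell (13 over the list alone; median -3.18, adjusted p = 2.28e-21), among them Akr1d1 (-6.13 ± 0.54), Slco1b2 (-5.99 ± 0.51) and Cyp8b1, the sterol 12-alpha-hydroxylase (-5.81 ± 0.60). Of 18 glucose and glycogen genes, 12 fell (14 over the list alone; median -1.72, adjusted p = 1.37e-15), among them the serine dehydratase Sds (-4.48 ± 0.69). Of 35 cytochrome P450 and xenobiotic genes, 24 fell (29 over the list alone; median -3.56, adjusted p = 4.95e-33), with Cyp3a41a at -7.07 ± 0.50, Cyp2c37 at -7.00 ± 0.76 and Cyp3a11 at -6.77 ± 0.66. These 4 lists passed with an estimated correlation as well (adjusted p = 0.0339 to 0.0429).

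Of 22 blood coagulation genes, 11 fell (15 over the list alone; median -2.33, adjusted p = 1.51e-16, and adjusted p = 0.0952 with an estimated correlation), led by the clotting factor F9 (-6.50 ± 0.52) and the kininogen gene Kng1 (-4.13 ± 0.71). Of 14 acute phase genes, 8 fell (9 over the list alone; median -2.23, adjusted p = 3.59e-10, adjusted p = 0.0933 with an estimated correlation), with the serum amyloid gene Saa4 at -7.55 ± 0.53, haptoglobin (Hp) at -3.77 ± 0.42 and Apcs at -3.36 ± 0.31. Of 19 complement genes, 7 fell (13 down and 1 up over the list alone; median -1.38, adjusted p = 4.84e-09, adjusted p = 0.208 with an estimated correlation), among them C4b (-5.91 ± 0.99) and C3 (-3.61 ± 0.78). Of 17 plasma carrier genes, Serpina6 rose and Fetub (-6.67 ± 1.09), Azgp1, Serpina7 and Cp fell (12 down and 1 up over the list alone; median -2.37, adjusted p = 1.1e-07, adjusted p = 0.181 with an estimated correlation). Albumin, the most abundant carrier, had a mean of 2449571.7 in WT and 452407.7 in the knockout and did not pass (-2.69 ± 1.51, adjusted p = 0.485). Of 20 apolipoprotein and lipoprotein genes, 7 fell (13 over the list alone; median -1.83, adjusted p = 1.54e-11, adjusted p = 0.137 with an estimated correlation), led by Apoc3 (-4.87 ± 0.66) and Apoa5 (-4.45 ± 0.68). Leaving out 1 library ended the call of C3 (WT replicates 1, 2 and 3 and C/EBPα knockout replicate 1; highest adjusted p = 0.113) and of Azgp1 (WT replicates 1 and 3 and C/EBPα knockout replicates 1 and 2; 0.0929).

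Of 23 fatty acid oxidation and ketogenesis genes, 3 fell, among them Acsl1 (-2.25 ± 0.38) and Acadm (-2.03 ± 0.31) (5 over the list alone; median -0.90, adjusted p = 1.75e-08, adjusted p = 0.112 with an estimated correlation). Of 17 fatty acid and triglyceride synthesis genes, Acacb, Scd1 (-2.47 ± 0.46) and Gpam fell (4 over the list alone; median -0.64, adjusted p = 0.0011, adjusted p = 0.243 with an estimated correlation). In the cholesterol synthesis list, Sc5d fell and 18 of 19 genes did not pass (1 over the list alone); the median was 0.22, the mean -0.01 and the test, which pointed up, did not pass (adjusted p = 0.649). Among 15 fetal liver genes, Hmga2 rose (2.16 ± 0.51; 2 up and 1 down over the list alone) and the list did not pass (median 0.04, adjusted p = 0.245). Calls ended with 1 library left out for Acacb and Sc5d (5 fits each, WT replicates 1 to 3 and C/EBPα knockout replicates 1 and 2, adjusted p up to 0.145 and 0.128), Gpam (3 fits, WT replicates 1 and 3 and C/EBPα knockout replicate 1, up to 0.0902) and Hmga2 (6 fits, all but WT replicate 3 and C/EBPα knockout replicate 3, up to 0.198).

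Of 25 liver transcription factors, Nr1i3 (-4.46 ± 0.82), Cebpa, Foxa1 (-3.46 ± 0.69) and the bile acid receptor Nr1h4 (-3.22 ± 0.36) fell and Gata6 rose (6 down and 1 up over the list alone; median -0.53, adjusted p = 0.000278, adjusted p = 0.266 with an estimated correlation). Of 25 cell cycle genes, all had estimates above 0, and cyclin D1 (Ccnd1, 1.86 ± 0.32), Plk1 (1.17 ± 0.28) and Ccne1 (1.16 ± 0.28) rose (6 over the list alone; median 0.75, adjusted p = 6.45e-10, adjusted p = 0.0776 with an estimated correlation). Among 14 epithelial junction genes, Cldn2 (3.08 ± 0.42) and Cldn3 (2.78 ± 0.54) rose while Cldn14, Gjb2 (-2.29 ± 0.38), Cldn1 and Ceacam1 fell (2 up and 5 down over the list alone), and the list did not pass (median -0.26, adjusted p = 0.09). Of 12 male-biased genes, Cyp2d9 (-4.71 ± 0.58), Ugt2b38 and Slco1a1 fell (6 over the list alone; median -1.85, adjusted p = 1.07e-05). Of 13 female-biased genes, 7 fell (11 down and 1 up over the list alone; median -5.00, adjusted p = 1.76e-14), led by Cyp2a4 (-7.48 ± 0.70), the sulfotransferase gene Sult3a1 (-7.36 ± 0.83) and Cyp3a41b (-7.08 ± 0.59). Both sex-biased lists passed with an estimated correlation (adjusted p = 0.0381 each). Y-linked genes were high only in WT replicate 1 and Xist varied within each genotype, so sex was not separated from genotype in these lists. Without WT replicate 1 both lists passed as well. Without WT replicate 1, adjusted p reached 0.0522 (Nr1i3), 0.103 (Foxa1), 0.071 (Gata6), 0.187 (Plk1), 0.155 (Ccne1), 0.104 (Cldn14), 0.0559 (Gjb2) and 0.165 (Ceacam1). The calls of Cldn3 (up to 0.067, without WT replicate 2) and Slco1a1 (up to 0.0997, without WT replicate 3) ended as well. Each of the other 7 libraries ended some of these calls: WT replicate 2 those of Foxa1, Gata6, Cldn14, Cldn3, Plk1 and Ccne1, WT replicate 3 those of Nr1i3, Slco1a1, Ceacam1, Plk1 and Ccne1, and each knockout library that of Plk1, with Ccne1, Ceacam1, Gata6 or Slco1a1 in most.

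Markers of other liver cells moved apart from each other. Of 9 bile duct markers, Cldn7 (4.01 ± 0.82), Sox9, the transcription factor of bile duct cells (2.90 ± 0.65), Prom1 (2.26 ± 0.44) and osteopontin (Spp1, 2.19 ± 0.48) rose (7 up and 1 down over the list alone; median 2.19, adjusted p = 0.000109, and 0.0429 with an estimated correlation). Their calls ended without WT replicate 1 (adjusted p up to 0.157 for Sox9 and 0.142 for Spp1), and also without WT replicate 2, 1 or more of the C/EBPα knockout replicates and, for Cldn7 (up to 0.0839), WT replicate 3. Other lists passed with no member called, none over the list alone either. These were erythroid cells (20 genes, median 0.35, adjusted p = 0.0267, adjusted p = 0.284 with an estimated correlation), endothelial cells (12 genes, -0.56, 0.0134, adjusted p = 0.137 with an estimated correlation), macrophages (12 genes, -0.45, 0.0338, adjusted p = 0.458 with an estimated correlation) and megakaryocytes (7 genes, -0.89, 0.0112, adjusted p = 0.176 with an estimated correlation). The most expressed of them were Hbb-b1 (-0.61 ± 1.39), Stab1 (0.08 ± 0.36), C1qb (-0.25 ± 0.62) and Pf4 (-1.05 ± 0.45). Without WT replicate 3 or C/EBPα knockout replicate 2, adjusted p was 0.125 and 0.0974 for erythroid cells, 0.0564 and 0.0696 for endothelial cells, and 0.0576 and 0.733 for macrophages, which were also lost without WT replicate 2 (0.0961). The megakaryocyte list was lost without WT replicate 2 (0.0792) or C/EBPα knockout replicate 1 (0.0892). Stellate cells and fibroblasts (11 genes, median -0.09, mean 0.01, test down, adjusted p = 0.915), lymphocytes (8 genes, -0.62, 0.177) and neutrophils and granulocyte precursors (9 genes, 0.11, 0.825) did not pass, with no member called.

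With each of the 8 libraries left out in turn, the count of 666 ranged from 311 (without WT replicate 1) to 804 (without C/EBPα knockout replicate 3); it was 402 without WT replicate 2 and 406 without C/EBPα knockout replicate 1. WT replicate 3 and C/EBPα knockout replicate 1 shared a GC trend (rank correlations of -0.40 and -0.37 with GC content), and without both 216 genes were called. Of 58 list members that the rule named and that passed, 34 passed in each of these 8 fits, and none changed direction. With library totals in place of the deposited scaling, 798 genes were called and 40.6% of them were lower, since the median of all genes then moved by 0.533; endothelial cells and macrophages no longer passed.

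The comparison of HNF4α knockout with WT livers asks the same for HNF4α. In the knockout, RNAs of bile acid, drug and amino acid enzymes were lower. Baat, which conjugates bile acids, fell 81.2-fold (log2 -6.34 ± 0.56, n = 2 and 3, adjusted p = 0.00026), and Mbl2, a complement lectin, 78.5-fold (-6.29 ± 0.45, adjusted p = 0.000171). Nnat (ENSMUSG00000067786), an imprinted gene, rose 97.9-fold (6.61 ± 0.48, adjusted p = 0.000171). In all, 273 genes were higher and 563 lower, 67.3% of 836, each at least 2-fold with no overlap. The rises rested more than the falls on knockout replicate 1, which held muscle RNA. Without overlap were 44.6% of all genes tested; chance gives 20% for 2 against 3.

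The 10 largest rises included Pvalb, Nnat, Ramp3, Hamp, Esm1, Cox4i2, Amy2a2, Hrc and Amy2a5. Nnat was at 25570 and 18922 in the knockout, against 202 to 261 in WT. Hamp, the iron hormone hepcidin, was at 1924 and 2780 against 8 to 72. The amylase gene Amy2a5 (ENSMUSG00000074268) was at 1195 and 2419 against 37 to 82, and its near copy Amy2a2 at 2156 and 6220 against 48 to 201. Esm1 rose 35.7-fold (5.16 ± 0.68), Ramp3 94.8-fold (6.57 ± 1.05) and Cox4i2 33.4-fold (5.06 ± 0.78), each high in both replicates. Pvalb, a calcium buffer of fast muscle, was listed at 0 in WT and at 893 and 33 in the knockout, and Hrc, which muscle also expresses, was at 1695 and 98, both highest in replicate 1. When HNF4α knockout replicate 1 was left out, Ramp3 (adjusted p = 0.0541), Cox4i2 (0.0614) and Hrc (0.501) did not pass; Hrc was also lost without WT replicate 1 or 3 or C/EBPα knockout replicate 1.

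That library held skeletal muscle RNA. All 13 skeletal muscle markers were more than 10 times as high in HNF4α knockout replicate 1 as in any other library. Alpha-actin (Acta1) was at 279927 there and at 94 in replicate 2, creatine kinase (Ckm) at 234321 and 20, and titin (Ttn) at 15199 and 6. No muscle marker passed alone; the list, chosen after seeing the data and with 3 of 13 members at a mean of 10 or more in WT, passed (median 6.79, adjusted p = 4.36e-06, adjusted p = 0.313 with an estimated correlation). C/EBPα knockout replicate 3 held a trace, with Ckm at 290 and Acta1 at 421.

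**Figure D2:**
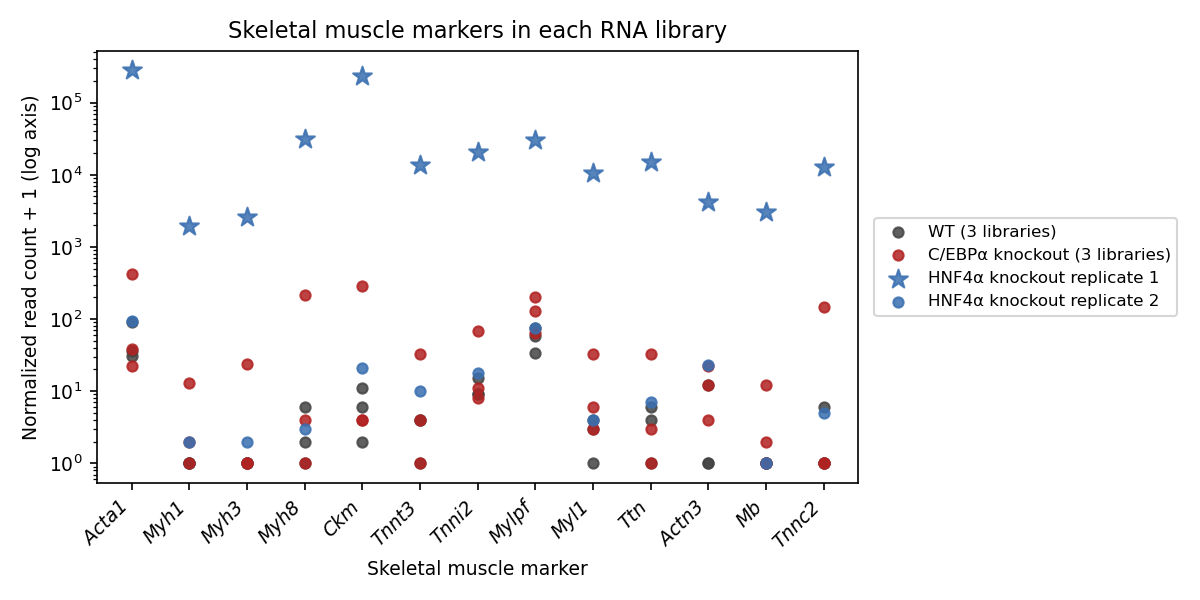
Normalized read counts plus 1, on a log axis, of 13 skeletal muscle markers in each of the 8 RNA libraries (points). HNF4α knockout replicate 1 (stars) lies above all other libraries for each marker, with Acta1 at 279927.

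The 10 largest falls included Serpina3k, Sult3a1, Cyp4a10, Inhbe, Cyp2c54, Cyp4a12b, Dnahc17, Cyp4a32 and Slc10a5. Serpina3k fell 268-fold (-8.06 ± 1.02), Cyp4a10, a fatty acid hydroxylase, 223-fold (-7.80 ± 0.86), and Inhbe, an inhibin subunit made in liver, 185-fold (-7.53 ± 0.90). Dnahc17, a dynein heavy chain, fell 137-fold (-7.10 ± 0.88). Cyp4a12b (-7.22 ± 1.31) did not pass without HNF4α knockout replicate 1 (adjusted p = 0.133).

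Of 35 cytochrome P450 and xenobiotic genes, 29 fell (30 over the list alone; median -3.79, adjusted p = 5.25e-30), led by Cyp4a10, Cyp2c54 (-7.28 ± 0.82), Cyp3a25 (-6.66 ± 0.92) and the ethanol-inducible Cyp2e1 (-6.39 ± 0.50). Of 20 bile acid genes, 16 fell (17 over the list alone; median -3.08, adjusted p = 2.59e-19), with Baat, Slco1b2 (-5.94 ± 0.57), Slc27a5 (-4.96 ± 0.59) and Cyp7a1, the rate-limiting enzyme of bile acid synthesis (-4.59 ± 0.47). Of 26 urea cycle and amino acid genes, 15 fell (16 over the list alone; median -1.91, adjusted p = 3.92e-14), among them Otc, of the urea cycle (-4.81 ± 0.39), and Kmo (-4.66 ± 0.50). Cps1 was at 23381 against 43356.7 and did not pass (-0.87 ± 0.66, adjusted p = 0.474). Of 18 glucose and glycogen genes, 6 fell (11 down and 1 up over the list alone; median -1.70, adjusted p = 1.69e-06), with glucose-6-phosphatase (G6pc, -4.96 ± 0.80) and the glycogen synthase Gys2 (-3.36 ± 0.31). These 4 lists passed with an estimated correlation (adjusted p = 0.0381 to 0.0442). G6pc did not pass without HNF4α knockout replicate 1 (0.0685).

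Of 19 complement genes, 12 fell (15 over the list alone; median -2.53, adjusted p = 5.88e-14, adjusted p = 0.137 with an estimated correlation), with Mbl2, C8a (-4.94 ± 0.56) and Masp2 (-4.23 ± 0.43). Of 22 coagulation genes, 8 fell (11 over the list alone; median -1.46, adjusted p = 4.53e-09, adjusted p = 0.178 with an estimated correlation), with F9 (-5.44 ± 0.58) and F13b (-4.80 ± 0.66). Of 20 apolipoprotein and lipoprotein genes, Apob, the structural protein of very low density lipoprotein (-4.96 ± 0.70), the lipase Lipc (-3.98 ± 0.42) and Mttp, which loads lipid on Apob (-2.70 ± 0.35), fell (7 over the list alone; median -1.41, adjusted p = 3.95e-05, adjusted p = 0.284 with an estimated correlation). In the plasma carrier list Serpina6 rose (4.60 ± 0.52; 2 up and 2 down over the list alone), albumin did not pass (-1.94 ± 1.69, adjusted p = 0.543) and nor did the list (17 genes, median -1.23, adjusted p = 0.0696). It passed without HNF4α knockout replicate 2 (0.0356) or C/EBPα knockout replicate 2 (0.0188) or 3 (0.0429). Among 14 acute phase genes, Hamp rose and Apcs (-2.91 ± 0.34), Itih4 (-3.28 ± 0.76) and Crp (-1.46 ± 0.37) fell (2 up and 5 down over the list alone), and the list did not pass (median -0.78, adjusted p = 0.266). Without HNF4α knockout replicate 1, Itih4 (0.281) and Crp (0.271) did not pass; both were also lost without any of the WT replicates or HNF4α knockout replicate 2, and Crp without C/EBPα knockout replicate 1.

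Of 23 fatty acid oxidation and ketogenesis genes, 9 fell (15 over the list alone; median -1.66, adjusted p = 7.33e-11, adjusted p = 0.0813 with an estimated correlation). They included Bdh1, of ketone body synthesis (-3.03 ± 0.42), the peroxisomal enzyme Ehhadh (-3.16 ± 0.59), the lipid receptor Ppara (-3.09 ± 0.69) and the fatty acid carrier Fabp1 (-2.53 ± 0.44). Of 17 fatty acid and triglyceride synthesis genes, Mlxipl (-2.03 ± 0.51), Elovl6 (-1.53 ± 0.37) and Gpam (-1.45 ± 0.35) fell (3 over the list alone; median -0.71, adjusted p = 0.0218, adjusted p = 0.336 with an estimated correlation); the list did not pass without WT replicate 3 (0.0649) or HNF4α knockout replicate 2 (0.0974). Of 19 cholesterol synthesis genes, Sc5d (-2.35 ± 0.39) and Lss (-1.97 ± 0.47) fell (7 over the list alone; median -0.89, adjusted p = 0.000668, adjusted p = 0.143 with an estimated correlation). None of 15 fetal liver genes was called (1 up over the list alone; median 0.40, adjusted p = 0.627). Without HNF4α knockout replicate 1, adjusted p rose to 0.0816 for Ehhadh, 0.278 for Ppara, 0.429 for Mlxipl, 0.334 for Elovl6, 0.34 for Gpam, 0.121 for Sc5d and 0.246 for Lss. All of these but Sc5d were also lost without WT replicate 1 and without HNF4α knockout replicate 2, which ended the call of Fabp1 too (0.0714, and 0.062 without replicate 1). WT replicates 2 and 3 and C/EBPα knockout replicate 1 ended some of them.

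Of 25 liver transcription factors, 7 fell (9 down and 1 up over the list alone; median -0.62, adjusted p = 0.00217, adjusted p = 0.315 with an estimated correlation), led by the xenobiotic receptors Nr1i3 (-4.74 ± 0.92) and Nr1i2 (-3.86 ± 0.45) and by Nr1h4 (-3.21 ± 0.40). Of 14 epithelial junction genes, 7 fell (8 over the list alone; median -1.57, adjusted p = 1.99e-07, and 0.0381 with an estimated correlation), with the connexin gene Gjb2 (-3.46 ± 0.43), Cldn1 (-3.41 ± 0.39), E-cadherin (Cdh1, -2.46 ± 0.37) and Ocln (-2.33 ± 0.51). Of 12 male-biased genes, 6 fell (7 over the list alone; median -3.55, adjusted p = 1.95e-06), with Keg1 at -5.56 ± 0.58, and of 13 female-biased genes, 8 fell (9 over the list alone; median -3.29, adjusted p = 7.72e-10), with Sult3a1 at -7.83 ± 0.92 and Cyp3a41a at -6.03 ± 0.56. Both passed with an estimated correlation (0.0381 and 0.0429) and without WT replicate 1, with the same limit from the sex of the livers. None of 25 cell cycle genes was called, none over the list alone either, and the list did not pass (median 0.32, adjusted p = 0.0511); it passed without HNF4α knockout replicate 1 (0.0013) or WT replicate 3 (0.0382). Without HNF4α knockout replicate 1, adjusted p rose to 0.112 for Nr1i3, 0.0578 for Cdh1 and 0.32 for Ocln; Nr1i3 and Ocln were also lost without WT replicates 1 and 3 or HNF4α knockout replicate 2, and Ocln without WT replicate 2.

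Among markers of other cells, stellate cell and fibroblast genes rose as a list, with 2 of 11 members below 0. Of 11, the smooth muscle gene Tagln (2.82 ± 0.40), collagens Col1a1 (2.80 ± 0.40) and Col1a2 (2.33 ± 0.45) and alpha-smooth muscle actin (Acta2, 2.42 ± 0.45) rose (7 over the list alone; median 1.67, adjusted p = 1.73e-05, and 0.0429 with an estimated correlation). Col1a1 was at 19659 and 11721 in the knockout against 1980 to 2294 in WT, higher in the replicate with muscle RNA. In replicate 2 alone Tagln was 2.94, Col1a1 2.42, Acta2 2.28 and Col1a2 1.80 above WT, while Lum (0.49), Reln (0.29), Lrat (0.02) and Dcn (0.01) lay close to it. Of 12 macrophage markers Cd68 rose (1.70 ± 0.42; 4 over the list alone; median 1.11, adjusted p = 0.00684, adjusted p = 0.336 with an estimated correlation). The 9 neutrophil and granulocyte precursor genes passed with none called, none over the list alone either (median 1.12, adjusted p = 0.00692, adjusted p = 0.336 with an estimated correlation). Erythroid cells (20 genes, median 0.68, adjusted p = 0.0532), endothelial cells (12 genes, 0.04, 0.558) and megakaryocytes (7 genes, 0.33, 0.558) did not pass, with no member called; erythroid cells passed without WT replicate 1 (0.0451) or C/EBPα knockout replicate 2 (0.0343) and with library totals. Of 9 bile duct markers Krt23 fell (-4.78 ± 0.78; 1 over the list alone), with a median of 0.45, a mean of -0.39 and a test that pointed down and did not pass (adjusted p = 0.925). Of 8 lymphocyte markers Klrb1c rose (4.10 ± 1.04; 1 over the list alone) and the list did not pass (median 0.46, adjusted p = 0.481). Without HNF4α knockout replicate 1, adjusted p rose to 0.0513 for Col1a1, 0.222 for Col1a2, 0.14 for Acta2, 0.326 for Cd68 and 0.0734 for Krt23; Col1a2 was also lost without WT replicate 1, Acta2 without HNF4α knockout replicate 2, and Cd68 without any WT replicate or HNF4α knockout replicate 2. Klrb1c was lost without any WT replicate or C/EBPα knockout replicate 1 or 2 (0.0898 at most).

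With each library left out in turn, the count of 836 ranged from 238 (without HNF4α knockout replicate 1) to 1372 (without C/EBPα knockout replicate 3); it was 372 and 504 without WT replicates 1 and 3 and 530 without HNF4α knockout replicate 2. Without WT replicate 3 and C/EBPα knockout replicate 1 it was 347, and 31 of 58 list members that the rule named and that passed did so in each of the 8 fits, with none changing direction. A single knockout library is assumed to vary like the other groups.

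**Figure D3:**
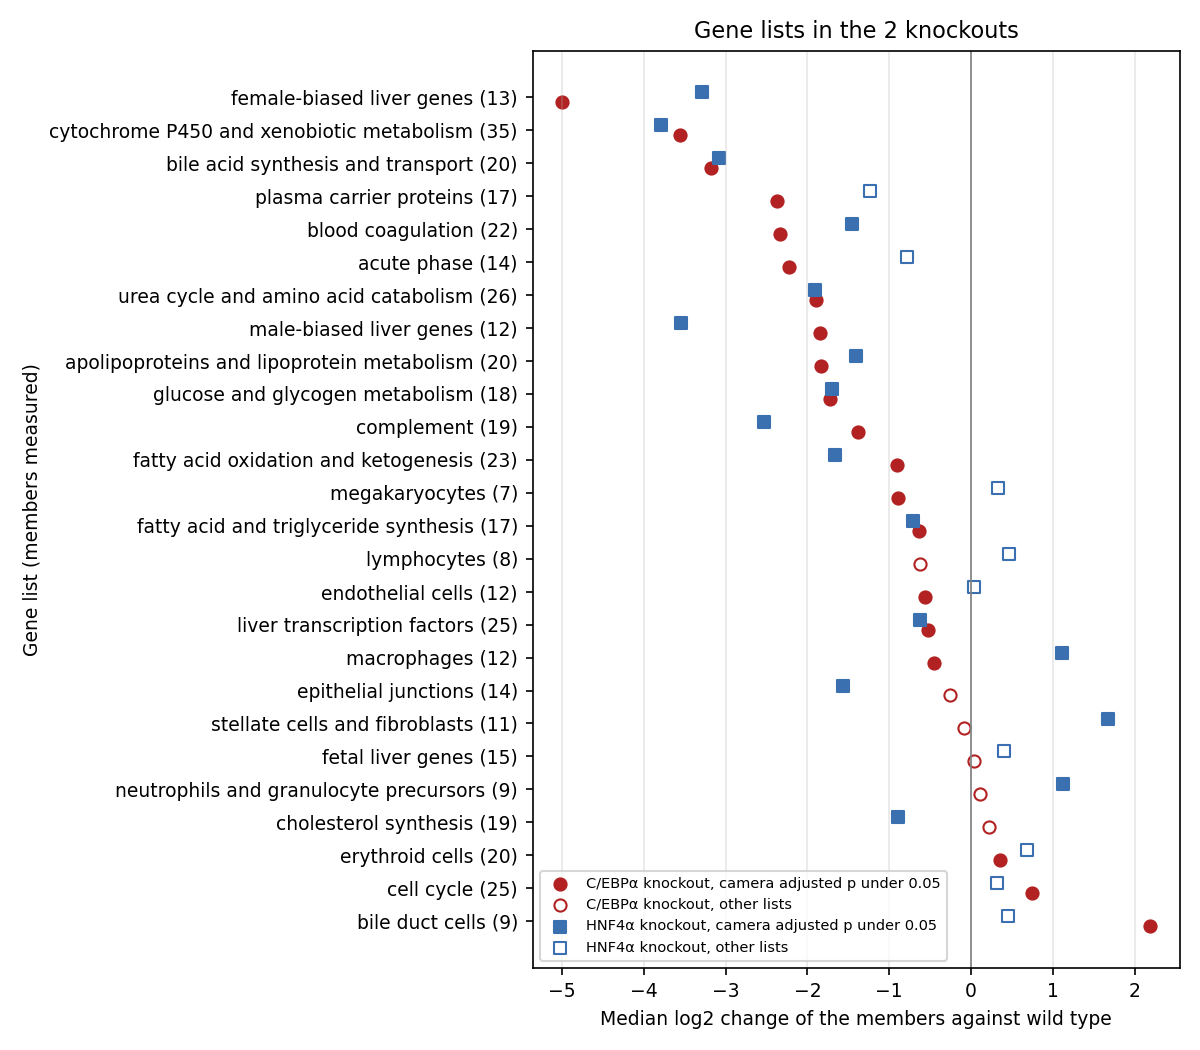
Median log2 change against WT of the measured members (number in brackets) of 26 gene lists in the C/EBPα knockout (circles) and the HNF4α knockout (squares); filled symbols passed camera. Bile duct markers have medians of 2.19 and 0.45, and stellate cell and fibroblast markers of -0.09 and 1.67.

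The comparison of the knockouts with each other tests directly where the loss of C/EBPα and of HNF4α differed. RNA of Cps1, the first enzyme of the urea cycle, was lower without C/EBPα, and RNA of Baat was lower without HNF4α. Cps1 was 108-fold lower in the C/EBPα than in the HNF4α knockout (log2 -6.75 ± 0.66, n = 3 and 2, adjusted p = 0.000912). Baat was 77-fold higher in the C/EBPα knockout (6.27 ± 0.56, adjusted p = 0.000761), with means of 927 and 9 against 828.3 in WT. Slc27a5, which also acts in bile acid conjugation, fell in both knockouts, and its difference between them did not pass (0.22 ± 0.59, adjusted p = 0.876). In all, 287 genes were higher and 332 lower (53.6% of 619) in the C/EBPα knockout. Without overlap were 34.4% of all genes tested, against 20% by chance.

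The 10 genes furthest above the HNF4α knockout were Cldn18, Bpifb1, Cym, Trim12a, Baat, Fabp2, Keg1, Spint1, Clic6 and Cldn7. Cldn18 was listed at 0 in the HNF4α knockout, and Keg1, a gene of liver and kidney, was 48.6-fold higher in the C/EBPα knockout (5.60 ± 0.58). The 10 furthest below included Saa3, Amy2a4, Amy2a3, Pvalb, Hamp, Amy2a2, Amy2a5, Cps1 and Vnn3. The amylase genes stood 152-fold (Amy2a5) to 192-fold (Amy2a4) below, Hamp 171-fold (-7.42 ± 0.99) and the pantetheinase gene Vnn3 83.4-fold (-6.38 ± 0.75). Pvalb was listed at 0 in the C/EBPα knockout and came mainly from the library with muscle RNA. Left without HNF4α knockout replicate 1, Trim12a (adjusted p = 0.111), Spint1 (0.0504), Cldn7 (0.0988) and Saa3 (0.119) did not pass; Trim12a (0.0529) and Saa3 (0.0576) were also lost without replicate 2.

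Of 26 urea cycle and amino acid genes, 8 were lower in the C/EBPα knockout and Otc (3.91 ± 0.39) and Kmo higher (11 and 4 over the list alone; median -0.33, adjusted p = 0.00767, adjusted p = 0.266 with an estimated correlation), with Tdo2, of tryptophan breakdown, at -5.81 ± 0.74 and Hpd at -5.14 ± 0.38. Of 14 acute phase genes, Hamp, Saa4 (-5.29 ± 0.59), Hp (-3.60 ± 0.47) and Lbp were lower (5 over the list alone; median -1.63, adjusted p = 7.58e-07, adjusted p = 0.143 with an estimated correlation). Of 17 plasma carriers, Serpina7 (-6.09 ± 0.62) and Cp were lower and Serpina6 higher (2.61 ± 0.52; 3 and 1 over the list alone; median -0.58, adjusted p = 0.0228, adjusted p = 0.496 with an estimated correlation). Of 19 complement genes, Cfb, C9 (4.19 ± 0.51), Mbl2 (3.24 ± 0.45), C8a and Masp2 were higher (9 up and 1 down over the list alone; median 1.07, adjusted p = 5.55e-05, adjusted p = 0.336 with an estimated correlation). Of 19 cholesterol synthesis genes, Lss, Cyp51 (1.68 ± 0.33) and Idi1 were higher (5 over the list alone; median 0.77, adjusted p = 7.3e-05, adjusted p = 0.112 with an estimated correlation). Of 23 fatty acid oxidation genes, Bdh1 was higher (2.61 ± 0.42; 4 over the list alone; median 0.49, adjusted p = 0.00807, adjusted p = 0.336 with an estimated correlation). Of 25 cell cycle genes, Ccnd1 was higher (1.54 ± 0.36; 1 over the list alone; median 0.45, adjusted p = 0.000949, adjusted p = 0.243 with an estimated correlation). Among these genes Cps1, Hpd, Otc, Hamp, Saa4, Serpina7, C9 and Mbl2 passed in each of the 8 fits. The others were lost without HNF4α knockout replicate 1 and some without further libraries, with adjusted p up to 0.43 (Idi1) and 0.397 (Cfb). The plasma carrier list was lost without C/EBPα knockout replicate 2 (0.41) or HNF4α knockout replicate 2 (0.274), and fatty acid oxidation without C/EBPα knockout replicate 3 (0.062) or HNF4α knockout replicate 2 (0.239).

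Epithelial genes were higher and stromal genes lower in the C/EBPα than in the HNF4α knockout. Of 14 epithelial junction genes, Cldn3 (3.76 ± 0.60), Cldn2 (3.01 ± 0.47), Ocln (2.62 ± 0.51), Cdh1 (2.34 ± 0.37) and Cgn were higher (8 up and 1 down over the list alone; median 1.11, adjusted p = 1.73e-05, and 0.0445 with an estimated correlation). Of 9 bile duct markers, Cldn7 (5.44 ± 0.91), Epcam (4.22 ± 0.82) and Spp1 (2.26 ± 0.54) were higher (5 over the list alone; median 1.70, adjusted p = 0.000214, and 0.0442 with an estimated correlation). Of 11 stellate cell and fibroblast markers, Col1a1 (-3.04 ± 0.40), Tagln (-2.91 ± 0.40), Acta2 (-2.53 ± 0.45) and Col1a2 (-2.06 ± 0.45) were lower (8 over the list alone; median -1.60, adjusted p = 4.29e-06, and 0.0429 with an estimated correlation). Of 12 macrophage markers, Cd5l (-2.25 ± 0.42) and Cd68 were lower (5 over the list alone; median -1.36, adjusted p = 1.11e-05, adjusted p = 0.194 with an estimated correlation), and of 12 endothelial markers, Flt1 was lower (4 over the list alone; median -0.63, adjusted p = 0.013, adjusted p = 0.137 with an estimated correlation). Lists lower with no member called were lymphocytes (8 genes, median -0.67, adjusted p = 0.0445, adjusted p = 0.176 with an estimated correlation; none over the list alone), neutrophils and granulocyte precursors (9 genes, -0.96, 0.00753, adjusted p = 0.336 with an estimated correlation; none) and megakaryocytes (7 genes, -1.02, 0.00809, adjusted p = 0.162 with an estimated correlation; 2 over the list alone). Each gene given in these lists was lost without HNF4α knockout replicate 1, with adjusted p from 0.0504 (Tagln) to 0.519 (Spp1), and some without further libraries. In that fit Tagln (-3.03), Acta2 (-2.39) and Col1a1 (-2.67) kept most of their difference, while Epcam went to 2.68 and Cldn7 to 3.74. The lymphocyte list was lost without C/EBPα knockout replicate 1 (0.108) or HNF4α knockout replicate 2 (0.416), and neutrophils without C/EBPα knockout replicate 3 (0.0887).

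The other 11 lists did not pass between the knockouts. They were bile acid (20 genes; Baat up, Akr1d1 and Slc10a1 down; median 0.20, adjusted p = 0.467; 3 up and 2 down over the list alone), glucose and glycogen (18; 2 up with Gys2, 2 down with Gbe1; -0.76, 0.115; 2 up and 4 down), and apolipoproteins (20; Apob, Mttp and Lipc up, and 3 down with Apoc1 and Apoc3; -1.10, 0.177; 4 up and 7 down). Of 22 coagulation genes Proz was up and Fgg down (-0.69, 0.15; 3 up and 3 down), and of 17 fatty acid and triglyceride synthesis genes Thrsp was down (-0.09, 0.745; 2 down). Of 35 cytochrome P450 and xenobiotic genes, Ugt2b36, Cyp4a10, Nr1i2, Cyp3a13 and Ugt2b1 were up and Ugt1a1, Ugt2b5 and Fmo1 down (0.28, 0.481; 8 up and 7 down). Among 25 liver transcription factors, Onecut1, Nr1i2 and Creb3l3 were up and Cebpa and Foxa1 down (0.08, 0.605; 3 up and 4 down). Of 12 male-biased genes Keg1 was up (0.52, 0.186; 2 up), and of 13 female-biased genes Acot3 and Hao2 were up and Cyp2a4 down (-1.29, 0.0666; 2 up and 5 down). No member of the fetal liver (15 genes, median 0.11, mean -0.04, test up, 0.692; 1 up over the list alone) or erythroid list (20 genes, -0.25, 0.854; none) was called. With 1 library left out, Baat, Slc10a1, Keg1, Acot3 and Hao2 passed in each fit, and the others named here were lost without HNF4α knockout replicate 1, with adjusted p up to 0.472 (Thrsp). Lists that passed with 1 library left out were apolipoproteins (without C/EBPα knockout replicate 3, 0.00821), coagulation (without it, 0.0172, or HNF4α knockout replicate 1, 0.0178), female-biased genes (without C/EBPα knockout replicate 1 or 3, 0.0413 and 0.0207, or HNF4α knockout replicate 1, 0.0401) and glucose and glycogen (without C/EBPα knockout replicate 3, 0.0246, or HNF4α knockout replicate 2, 0.0489).

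The count of 619 ranged from 88 (without HNF4α knockout replicate 1) to 855 (without C/EBPα knockout replicate 3) with each library left out; it was 378, 256 and 384 without WT replicate 1, C/EBPα knockout replicate 1 and HNF4α knockout replicate 2, and 138 without WT replicate 3 and C/EBPα knockout replicate 1. With library totals 800 genes were called and 21.1% were lower, with the median of all genes at 0.575, and the female-biased list passed.

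Genes changed in both knockouts were mostly lower: 261 were lower and 31 higher in both, and 4 changed in opposite directions. With library totals in place of the deposited scaling, 176 were lower and 52 higher. With each library left out in turn, 110 to 345 were lower in both, 6 to 30 higher and 0 to 12 opposite (0 without WT replicate 2 or 3, 12 without C/EBPα knockout replicate 3). Lower in both were Serpina3k, Sult3a1, Cyp3a25, the bile acid carrier Slco1b2, F9, Cyp2e1 and Slc27a5; Slco1b2 stood at 60.7 and 56.5 against 3864 in WT. Higher in both were Serpina6, the transcription factor genes Etv4 (4.02 ± 0.67 and 3.75 ± 0.75) and Onecut3 (3.53 ± 0.69 and 5.32 ± 0.77), the chemokine gene Cxcl10 (4.50 ± 0.55 and 3.60 ± 0.61), the growth factor gene Bmp7 (3.56 ± 0.49 and 4.16 ± 0.55), Timp1 and Sel1l3. The shared genes made up 51.3% of those lower in the C/EBPα knockout and 46.4% of those lower in the HNF4α knockout; 38 of the 292 also differed between the knockouts. Both comparisons use the same WT livers. In 100 simulations of unchanged groups against shared WT livers, lists of the same length shared 109.4 lower genes on average and 131 at most, and 32.4 higher genes, 45 at most. The log2 changes correlated across genes with r = 0.46, and 0.45 in the simulations; the covariance was 0.63, and 0.20 in them; genes are not independent replicates. The count of 292 ranged from 119 (without WT replicate 1) to 375 (without C/EBPα knockout replicate 3); it was 187 and 193 without WT replicates 2 and 3, 121 and 159 without HNF4α knockout replicates 1 and 2, and 92 without WT replicate 3 and C/EBPα knockout replicate 1. In the HNF4α knockout Etv4 (up to 0.142), Timp1 (0.124) and Cxcl10 (0.0579) lost their calls without replicate 1 or 2, Timp1 also without WT replicate 1. Sel1l3 lost it without replicate 1 (0.562), any WT replicate or C/EBPα knockout replicate 1. In the C/EBPα knockout Sel1l3 (0.145), Timp1 (0.0869) and Onecut3 (0.0804) lost theirs without WT replicate 1. There Sel1l3 was also lost without WT replicate 2 or C/EBPα knockout replicate 1 or 3, and Onecut3 without C/EBPα knockout replicate 2.

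The ChIP-seq lists ask where each factor was bound from E15.5 to P60, and how much of the early binding continued. Regions found in both replicates numbered 10418 for C/EBPα at E15.5, 65012 at E18.5, 94607 at P0.5, 34734 at P14 and 44216 at P60. For HNF4α they were 35763, 18369, 21262 (1 library), 23799 and 36321. The regions covered 4.7 Mb (C/EBPα, E15.5) to 43.5 Mb (C/EBPα, P0.5), and 12.2% to 29.3% of them lay within 5 kb of a TSS. On average, lists of the same stage resembled each other more than lists of other stages, with mean Jaccard indices of 0.513 against 0.271 for C/EBPα and 0.483 against 0.236 for HNF4α. The 1-sided exact permutation p was 0.0011 for each factor, the smallest that 945 groupings can give. Not every pair followed this: the C/EBPα lists at P60 shared 0.381 with each other and 0.369 to 0.396 with those at P14, and E18.5 replicate 1 shared 0.515 with its replicate and 0.55 and 0.544 with the P0.5 lists. Both HNF4α lists at E18.5 stood apart: their index with each other was 0.18, against 0.529 to 0.637 at the other replicated stages, and they overlapped the neighbouring stages at 0.124 (E15.5) and 0.103 (P0.5), while E15.5 and P0.5 shared 0.296.

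Of regions bound by C/EBPα at E15.5, those found again later by any overlap were 96.6% at E18.5, 97.3% at P0.5, 84.9% at P14 and 79.1% at P60, against 1.75% to 3.21% for shuffled regions. HNF4α regions of E15.5 were found again at 22.2% (E18.5), 50.0% (P0.5), 46.7% (P14) and 55.4% (P60), against 0.76% to 2.15%. With 50% reciprocal overlap it was 82.4%, 80.4%, 33.7% and 52.6% for C/EBPα and 18.3%, 33.3%, 30.2% and 38.8% for HNF4α, so at P14 the shares were close. The number of C/EBPα regions at E15.5 was the lowest of the 10 sets, so these shares rest on unequal lists. Seen from P60, 82.3% of 43312 merged C/EBPα regions were bound at an earlier stage and 69.6% before birth; for HNF4α it was 71.8% and 53.4% of 35554. At every stage, C/EBPα was found at 7670 of 107796 merged regions (7.1%) and HNF4α at 5757 of 63929 (9.0%). Only before birth, it was 4340 (4.0%) for C/EBPα and 21867 (34.2%) for HNF4α. Bound at P14 and P60 alone were 1708 (1.6%) and 4004 (6.3%). Without the E18.5 lists, HNF4α was found at all stages at 11989 of 54058 regions (22.2%) and only before birth at 11996 (22.2%), and C/EBPα at 7679 (7.4%) and 182 (0.2%) of 103638. In these, 18.6% of P60 regions of C/EBPα and 52.3% of those of HNF4α were bound before birth. Between single lists, the share kept at P60 was 72.1% to 84.5% for C/EBPα and 53.1% to 59.0% for HNF4α.

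**Figure D4:**
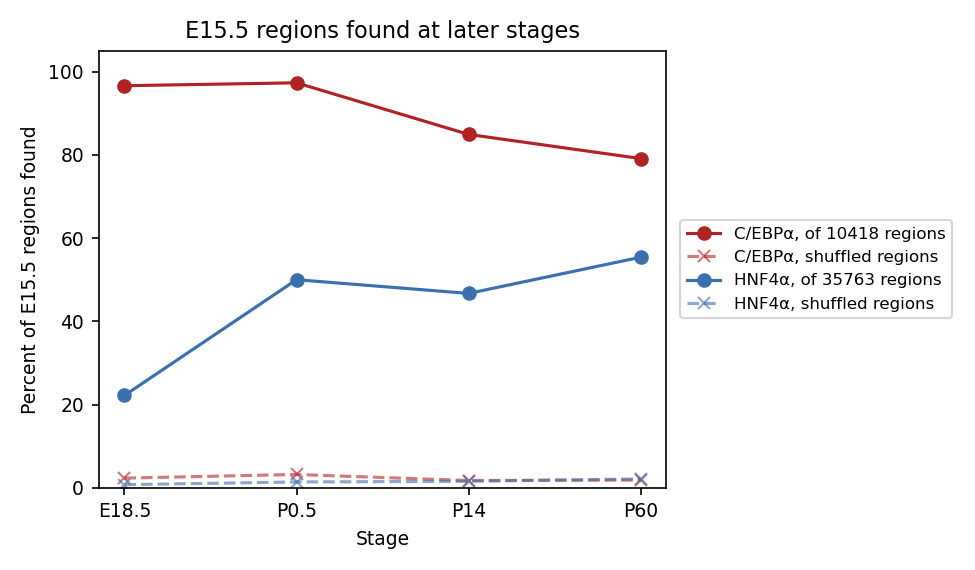
Percent of the regions bound at E15.5 that overlapped a region of the same factor at each later stage (circles), and the mean for shuffled regions (crosses). C/EBPα falls from 96.6% at E18.5 to 79.1% at P60, and HNF4α is at 22.2% at E18.5 and 55.4% at P60.

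Regions of C/EBPα and HNF4α overlapped more often than shuffled regions at each stage. Of C/EBPα regions, 55.0% overlapped HNF4α at E15.5, 9.1% at E18.5, 17.9% at P0.5, 40.9% at P14 and 48.1% at P60. Of HNF4α regions, 15.8%, 31.8%, 70.3%, 57.9% and 55.8% overlapped C/EBPα. Between single lists, these shares ranged for C/EBPα over 47.9% to 56.3%, 8.0% to 13.7%, 15.9% to 17.1%, 39.7% to 43.8% and 35.7% to 54.3%. For HNF4α they ranged over 14.7% to 20.2%, 17.9% to 20.9%, 73.1% to 75.4%, 58.4% to 61.0% and 50.3% to 68.2%, so at E18.5 the share of 31.8% was above all single lists. Shuffled regions reached 5.89% at most, and p was 0.0099 at each stage, the smallest that 100 shuffles can give. Both factors were bound at the albumin gene at all stages, with a region over its TSS (chromosome 5, 90889915) that spanned 90889586 to 90890005 for C/EBPα at E15.5 and 90889330 to 90890113 for HNF4α at P60. Both had regions within 5 kb of the TSS of Cebpa (chromosome 7, 35904312), Afp, G6pc and Apoa1 at all 5 stages. Within 5 kb, Hnf4a had C/EBPα at E18.5 and P0.5 and HNF4α at none. Cyp7a1 had C/EBPα from E18.5 on and HNF4α at each stage but E18.5, and Cps1 had C/EBPα at all stages and HNF4α at E15.5, P14 and P60. Of genes lower in both knockouts, Serpina3k, Cyp3a25 and Cyp4a10 had both factors at P60. Sult3a1 had C/EBPα at E18.5 and P0.5 only and HNF4α at no stage. Saa3 had C/EBPα at all stages and HNF4α at each stage but E18.5. Bpifb1 had HNF4α before birth and at P0.5 and C/EBPα at no stage, and Cldn18 and Amy2a4 had neither at any stage.

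**Figure D5:**
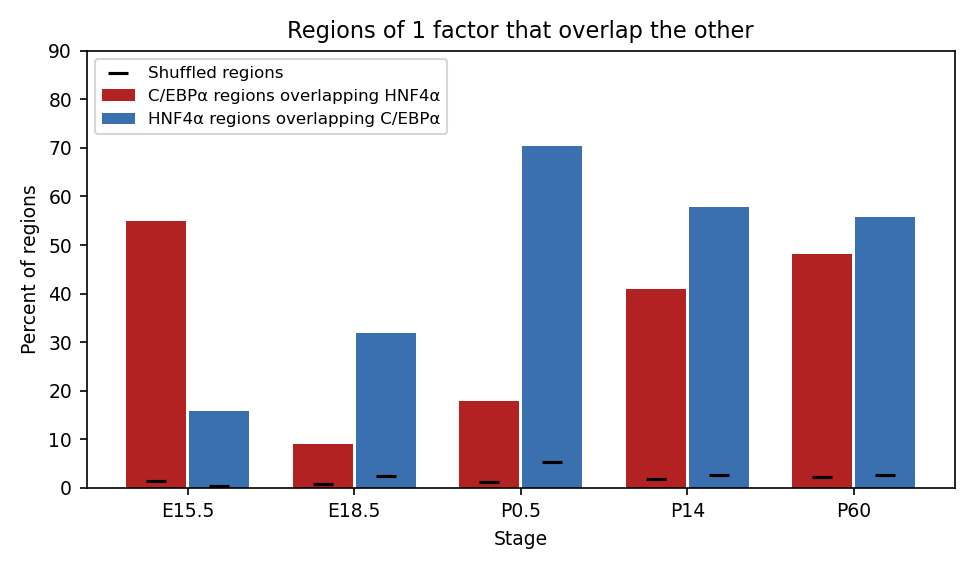
Percent of regions of each factor that overlapped the other at the same stage (bars), with the mean of shuffled regions (black marks). HNF4α lies at 15.8% at E15.5 and 70.3% at P0.5, on unequal lists.

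Genes of the liver lists were bound more often than other genes. At P60, 16 of 18 pathway lists were bound more often by C/EBPα and 14 by HNF4α (Fisher's exact test, adjusted), and none less often; of 8 lists of other cell types, none was bound more often and 1 less often, for each factor. Genes that fell in a knockout were bound more often than genes not called, at each stage and for both factors. HNF4α had a region near 480 of 563 genes (85.3%) that fell in the HNF4α knockout at P60, against 38.8% of genes not called (odds ratio 9.13, 95% interval 7.20 to 11.7, adjusted p = 7.63e-110, Fisher's exact test). C/EBPα at P60 had a region near 409 of 509 genes (80.4%) that fell in its own knockout, against 39% (odds ratio 6.40, 5.12 to 8.06, adjusted p = 4.59e-78). Binding was not particular to the factor lost. HNF4α lay near 419 of these 509 genes (82.3%, odds ratio 7.31). C/EBPα lay near 78.3% of genes that fell in the HNF4α knockout (odds ratio 5.63). At E18.5 the odds ratios for the factor lost were 7.43 (HNF4α) and 5.95 (C/EBPα). All 20 tests of genes that fell passed, with odds ratios of 3.17 to 9.13. Of 20 tests of genes that rose, 18 passed; 17 of these had odds ratios under 1, and genes higher in the C/EBPα knockout were bound more often by HNF4α at E15.5 (47.8% against 37.2%, odds ratio 1.55, adjusted p = 0.00915). With genes compared within bins of mean expression, 31 of 40 tests passed, 20 for genes that fell. Within 50 kb of the TSS, all 20 tests of genes that fell passed and none of genes that rose.

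Of the binding classes, genes bound at every stage had the lowest median changes. The 2230 genes with C/EBPα at every stage had a median log2 change of -0.22 in the C/EBPα knockout, where 200 fell and 7 rose (camera adjusted p = 1.56e-06, and 0.0301 with an estimated correlation). The 1796 genes with HNF4α at every stage had a median of -0.49 in the HNF4α knockout, where 241 fell and 12 rose (adjusted p = 1.55e-08, and 0.0457 with an estimated correlation). The shift was not particular to the factor lost: the same C/EBPα class had a median of -0.24 in the HNF4α knockout, where 180 fell (adjusted p = 0.00197, and 0.0457 with an estimated correlation). The HNF4α class had -0.28 in the C/EBPα knockout, where 193 fell (3.82e-08, and 0.0457). Genes never bound moved up relative to others, with medians of 0.15 (C/EBPα; 37 fell and 73 rose, adjusted p = 0.0081, and 0.0416 with an estimated correlation) and 0.19 (HNF4α; 53 fell and 170 rose, adjusted p = 0.000698, and 0.0301). The 136 genes with C/EBPα only before birth (0.07, adjusted p = 0.23) and the 1175 with HNF4α only before birth (0.11, 0.119) did not pass in the knockout of the same factor. Of 20 tests of binding classes 9 passed, and within 50 kb of the TSS none did.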

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

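Each explanation in this part was tested after the results were seen, whereas the comparison of the knockouts was planned. Among the results that differed between the knockouts, 4 genes were called in opposite directions. Krt20, a keratin of intestinal epithelium, was higher in the C/EBPα knockout (2.05 ± 0.45, adjusted p = 0.0283) and lower in the HNF4α knockout (-2.11 ± 0.50, adjusted p = 0.0378), a difference of 4.17 (adjusted p = 0.00222). The amylase genes Amy2a3, Amy2a4 and Amy2a5 went the other way, with differences of -7.57, -7.58 and -7.25. Without 1 library the Krt20 calls reached adjusted p of 0.147 (WT replicate 1, also lost without WT replicate 2 and C/EBPα knockout replicates 1 and 2) and 0.381 (HNF4α knockout replicate 1, also lost without its replicate 2, WT replicates 1 and 3 and C/EBPα knockout replicate 1). The lower calls of Amy2a3, Amy2a4 and Amy2a5 reached 0.0673, 0.117 and 0.105, ended by each WT replicate and C/EBPα knockout replicate 2. Both HNF4α knockout replicates ended those of Amy2a4 and Amy2a5, and C/EBPα knockout replicate 3 that of Amy2a4, whose higher call ended without HNF4α knockout replicate 2 (0.0577). Reads shared between these near copies were not separated here.

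The medians of 3 lists also differed between the knockouts, by the test of the difference itself: epithelial junctions by 1.11, bile duct markers by 1.70 and stellate cell and fibroblast markers by -1.60. For the count of 666 genes changed in the C/EBPα knockout, the 10 splits of the 6 libraries are too few for a share under 0.05. In 1 of the 10, the real split, 666 genes were called, and the highest of the others gave 0.

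Muscle and stromal RNAs were higher in the HNF4α knockout. All 13 skeletal muscle markers were at least 10-fold above the other 7 libraries in HNF4α knockout replicate 1, and 1 of 13 was higher in replicate 2 than in the 6 other libraries, so a rise of muscle genes in hepatocytes that lack HNF4α was not seen in both. Muscle tissue in replicate 1 is a candidate source of these RNAs. It does not account for all of the rise in stromal markers, whose median without that library was 1.13, with 11 of 11 above 0. That rise was uneven. Dcn (0.01), Lrat (0.02), Reln (0.29) and Lum (0.49) lay close to WT, and Tagln (2.94) and Col1a1 (2.42) highest. A lower share of hepatocyte RNA would raise other cell types alike. Stellate members stood 1.17 (SE 0.45 across genes) above the 77 members of the other cell type lists, with means of 1.63 and 0.46. This includes Des, at 31081 in replicate 1 and 612 in replicate 2. Genes of a list are not independent replicates, so the SE gives no spread between livers. Without HNF4α knockout replicate 1 the distance was 0.78 (SE 0.32), and 1.56 (SE 0.67) without replicate 2. The lists did not rise alike, as endothelial markers had a median of 0.04, but with 2 knockout livers a lower share alone was not excluded. Macrophage and neutrophil markers had medians of 1.11 and 1.12, close to the stromal median without replicate 1. A change in the stromal or other cells, or in their number, stays open.

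Bile duct markers were higher in the C/EBPα knockout. Their mean stood 1.70 (SE 0.66 across genes) above that of 79 members of the other cell type lists (1.51 against -0.19). Scaling moves all lists alike, so the distance argues against a lower hepatocyte share alone. This SE gives no spread between livers. With the GC trend between libraries removed, 3 of 4 called markers passed. Sox9 went from 2.90 ± 0.65 to 2.79 ± 0.71 and lost its call (adjusted p = 0.0569), as its error grew. More bile duct cells, or their genes in other cells, could each give these values and stay open.

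The HNF4α peak lists at E18.5 stood apart. The E15.5 and P0.5 lists shared a Jaccard index of 0.296, and the E18.5 lists 0.124 and 0.103 with them and 0.18 with each other. The E18.5 HNF4α lists shared 0.06 (0.052 to 0.067) with the E18.5 C/EBPα lists, below 0.102 (0.073 to 0.131) with HNF4α lists of other stages. This argues against use of the C/EBPα antibody. Of 18369 E18.5 regions in both replicates 44.7% were found at E15.5 or P0.5, and of 56545 peaks in 1 replicate 14.8%. The ratio was 0.33 (0.3 and 0.35), and shuffled regions gave 1.73%. Ratios of other stages had other references and are not compared. With replicates this unlike and no scores, weak enrichment, gradual change and a true difference at E18.5 cannot be told apart.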

How the results depend on the processing

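Quantile normalization, removal of the GC trend, the other added constants and the removal of WT replicate 3 with C/EBPα knockout replicate 1 were chosen after seeing the data. So were library totals for genes in both knockouts and for lists, the GC trend with a replicate block, the lists without a filter, and binding without the E18.5 lists. Of 127 alternative values of the leading results, 87 stayed within the stated limits and 40 moved. Of the values of single genes, lists and stages, 6641 kept direction and side of the threshold, 913 no longer passed, 44 passed only under the alternative, 44 moved and 4 reversed. Where values changed below, the cause was not tested unless given.

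With each library left out, genes changed in the C/EBPα knockout numbered 311 to 804 (666 with all libraries), in the HNF4α knockout 238 to 1372 (836), between the knockouts 88 to 855 (619) and in both knockouts 119 to 375 (292). The lowest counts came without WT replicate 1 (C/EBPα knockout, both) or HNF4α knockout replicate 1, and the highest without C/EBPα knockout replicate 3. Without WT replicate 3 and C/EBPα knockout replicate 1, which shared a GC trend, the counts were 216, 347, 138 and 92, with fewer libraries in the fit. With only the compared groups in the fit, 1475 genes changed in the HNF4α knockout and 343 differed between the knockouts. Without a filter 403 differed between the knockouts, with more genes tested. Library totals gave 798, 765 and 800 genes, quantile normalization 634, 794 and 605, and removal of the GC trend 758, 752 and 639. No named call reversed under these settings.

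Replicate numbers do not pair the libraries. A replicate block gave 509, 486 and 288 genes in the 3 comparisons and 181 in both knockouts, and with the GC trend removed 626, 504, 345 and 206. The correlation of deviations between libraries of the same number was -0.06 (WT and C/EBPα knockout replicates 1), 0.19 (replicates 2) and -0.23 (replicates 3). Within blocks, stage similarity of peak lists had an exact permutation p of 0.0083, the smallest that 120 groupings can give.

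Of the 78 list tests, 52 passed, 18 with an estimated correlation, 44 with fry, and 49 to 55 with each library left out.

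A peak in either replicate gave 408219 C/EBPα and 240238 HNF4α regions summed over stages, against 248987 and 135514, since it asks for less. With 50% reciprocal overlap, which asks for more, retention at P60 was 52.6% for C/EBPα and 38.8% for HNF4α, and mean co-binding was 25.6% of C/EBPα and 33.8% of HNF4α regions. Without replicate 1 or 2, retention was 72.6% to 82% (79.1% with both) and 53.8% to 57% (55.4%), and mean co-binding 31.7% to 34.4% and 44.1% to 47.8%.

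Of 40 tests of bound genes, 38 passed within 5 kb of the TSS, 35 within 1 kb and 20 within 50 kb, all of genes that fell. Of 20 tests of binding classes, 9 passed within 5 kb, 16 within 1 kb and 0 within 50 kb, where camera gave no class an adjusted p under the threshold. At 50 kb the odds ratio of genes higher in the HNF4α knockout reversed to 1.29 (C/EBPα, E18.5), 2.05 (C/EBPα, P0.5), 1.31 (HNF4α, E15.5) and 1.11 (HNF4α, P0.5).

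Not run, though listed beforehand, were other count-based tests and size factors, since the values are not counts, and those based on peak scores, since all scores are 0. The test planned as an alternative, limma on log2 values, became the test used. With the spread and number of these libraries, 4.3% of simulated 2-fold changes were recovered in the C/EBPα and 1.7% in the HNF4α contrast; depth was not varied.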

Other observations

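The lists, gene readings and hypotheses in this part were chosen after seeing the data. Of 8 intestinal genes, 6 of them at a mean of 10 or more in WT, Vil1 (3.10 ± 0.47, adjusted p = 0.00326), Fabp2 (3.14 ± 0.67, adjusted p = 0.0259) and Krt20 were higher in the C/EBPα knockout (median 1.63, camera adjusted p = 0.0441, adjusted p = 0.177 with an estimated correlation). Fabp2 did not pass without any of the WT replicates or C/EBPα knockout replicate 1 or 2 (0.127 at most), and Krt20 without WT replicate 1 or 2 or C/EBPα knockout replicate 1 or 2 (0.147 at most). In the HNF4α knockout Krt20 was lower (median of the list -0.75, adjusted p = 0.0468, adjusted p = 0.177 with an estimated correlation), which ended without HNF4α knockout replicate 1 (0.381) or 2, WT replicate 1 or 3 or C/EBPα knockout replicate 1.

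Stomach genes (3, with 2 at a mean of 10 or more in WT) had a median of 1.51 in the C/EBPα knockout (adjusted p = 0.0468, adjusted p = 0.177 with an estimated correlation) and 0.78 in the HNF4α knockout (adjusted p = 0.5), where Atp4a was higher (3.16 ± 0.61, lost without HNF4α knockout replicate 1 or 2 or WT replicate 1, 0.137 at most). Kidney tubule genes (2, both expressed in WT) had medians of -2.42 (adjusted p = 0.036, adjusted p = 0.177 with an estimated correlation) and -0.84 (adjusted p = 0.5). Pancreatic acinar genes (5, with 2 expressed) had medians of 0.69 (adjusted p = 0.635) and 2.17 (adjusted p = 0.017, adjusted p = 0.177 with an estimated correlation). Smooth muscle genes (7, with 6 expressed) had medians of 0.48 (adjusted p = 0.5) and 2.67 (adjusted p = 1.08e-05, adjusted p = 0.177 with an estimated correlation), with Acta2 and Actg2 higher in the HNF4α knockout. Actg2 (4.18 ± 0.74) was lost without HNF4α knockout replicate 1 or 2 (0.0734 at most) and Acta2 (2.42 ± 0.45) without the same libraries (0.14 at most). Desmin (Des) was at 31081 and 612, following the muscle RNA of replicate 1. In the C/EBPα knockout skeletal muscle genes had a median of 1.53 and did not pass (adjusted p = 0.155).

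The imprinted gene Meg3 was at 34113 to 54550 in the C/EBPα knockout and at 6854 to 9346 in WT (2.49 ± 0.42, adjusted p = 0.00672, 0.0741 without WT replicate 1), and at 17052 and 21468 in the HNF4α knockout, which did not pass (adjusted p = 0.175). The difference between the knockouts did not pass either (1.27 ± 0.47, adjusted p = 0.187). The labels give male mice. Xist was at 92, 5915 and 27836 in WT, at 21957, 4470 and 13318 in the C/EBPα knockout and at 1040 and 3941 in the HNF4α knockout. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d were at 1317, 1035, 276 and 297 in WT replicate 1 and at 109 or less in the other libraries. These 7 libraries go against the label, and pooled or mislabelled livers were not excluded.

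Genes lower in both knockouts may be those bound by both factors at P60. Of 4861 genes with both 218 (4.48%) were lower in both knockouts, against 7 of 2258 with C/EBPα alone, 12 of 2258 with HNF4α alone and 24 of 8394 with neither. Compared with genes that had 1 factor, within bins of mean expression, the odds ratio was 11.4 (95% interval 7.09 to 18.3, Mantel-Haenszel), and Fisher's exact test gave 11.1 (6.93 to 18.8). Genes that fell in 1 knockout only were also more often bound by both, with odds ratios of 3.02 (2.18 to 4.19, C/EBPα knockout) and 4.01 (2.93 to 5.47, HNF4α knockout). The labels and the series text differ on the age of the RNA samples. Levels of Afp and H19 in WT argue against 60 days, so E18.5 is closer to the RNA than P60. For genes lower in both knockouts the odds ratio was 2.99 at E15.5, 6.07 at E18.5 (4.68 to 7.88), 5.99 at P0.5 and 8.56 at P14.

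HNF4α regions of E15.5 that also hold C/EBPα may be kept longer. At P60, 75.0% of 5668 such regions were found again and 51.7% of 30095 others. Compared within 5 bins of region width, the difference was 16.9 percentage points (8.7 to 22.6 across the bins).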
